A study of Mus musculus with 4 samples.

How the data were processed

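RNA from 4 cultures of primary mouse articular chondrocytes, the cells that make and maintain joint cartilage, was measured on single-colour expression arrays. The design text describes 2 biological replicates that received the control adenovirus Ad-C and 2 that received Ad-Rip3, an adenovirus that carries Rip3 (gene symbol Ripk3; Ad is read as adenovirus, which the labels do not spell out), with RNA taken 36 hours after infection. Per the labels' protocols, total RNA was extracted with a commercial kit, and sense-strand cDNA was fragmented and labelled with biotin for GeneChip whole-transcript arrays. The background correction, the normalization and the way probe signals were combined are not given in the sources used here.

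The values deposited by the authors are treated as log2 signals, 1 for each of 31873 array rows and each array. The log scale follows from the values, which ran from 0.976 to 13.0; base 2 was inferred from that range and is not stated. The medians of the 4 columns lay between 4.97 and 5.05, so the columns had nearly the same distribution as deposited, and rows were not centred. No detection calls came with the values, so whether a dim row is above background could not be judged, and a fold change of a dim row can be smaller than the change in RNA. Arrays carry no sequencing depth, and their number, 2 per group, limits the precision.

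Rows were named through GEO's platform annotation: 23094 rows carried 1 gene symbol, 1764 carried several and 7015 were unlisted. The 8779 rows of the last 2 kinds were not used in the comparison. The named rows covered 22087 genes, of which 21921 matched an Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, used only for names and for which genes are neighbours. For the 810 genes with several rows, the row with the highest mean over the 4 arrays was kept. No coordinates are given because the build behind the array annotation is not stated.

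The comparison was Ad-Rip3 minus Ad-C, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior variance, no covariate, no filter on dim rows) and adjusted with the Benjamini-Hochberg method at 0.05 over all 22087 genes. Calls over all genes are those of this fit unless another setting is named. Errors of log2 fold changes are the standard errors of this moderated fit, and group values are means ± SD over 2 arrays. Beside it stands a count, without a p-value, of genes whose group means lay at least 2-fold apart with both Ad-Rip3 arrays on the same side of both Ad-C arrays.

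Before the data were examined, 23 gene lists were fixed (429 genes, 10 of them in more than 1 list). Of these genes, 389 had a row of their own and were used; the others were not analysed here. Each list was tested with camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated per list and with fry; p-values were adjusted over the 23 lists. The genes named in the text were set by a rule written at the same time: Ripk3; the 10 largest rises and up to 10 largest falls past the threshold, leaving out predicted gene models, microRNAs and olfactory and vomeronasal receptors; for each list up to 4 members past the threshold or, if none passed, the 2 with the smallest p; and always Mmp3, Mmp13, Adamts5, Il6, Ptgs2, Col2a1, Acan and Sox9. Where fewer than 10 passed in a direction, genes 2-fold apart without overlap were to fill up the 10; only 6 falls qualified and no such gene was left to add. Predicted models here are symbols of the Gm, LOC, Rik, Snor and n-R5s kinds.

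The fit was tested on simulated data: in 10 simulations with the genes' own mean levels, a spread drawn from the fitted intensity trend and 200 changed genes among 22087, it recovered 72.3% of 2-fold and 99.4% of 4-fold changes, with 2.39% of its calls false. With an intensity trend in the prior variance the shares were 88.1% and 100%, with 4.86% of calls false, in data made with such a trend. Camera at the preset correlation called 1.9% of unshifted lists of 20 genes at an unadjusted 0.05, and all 10 lists shifted by 0.3. With the correlation estimated, it called 0% of unshifted lists and also all 10 shifted lists, again at an unadjusted 0.05. Simulated genes varied independently, unlike genes of a real list, and the real lists were judged on adjusted p-values. The simulation therefore does not show that camera with an estimated correlation, as used on the real lists, can detect such shifts.

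The alternatives were a prior variance with an intensity trend (plain and robust), leaving out the dimmer part of the genes (means under the median level) and averaging a gene's rows. Others were testing every row, quantile normalization of the deposited values, centring arrays on their medians, the replicate number as a block, and leaving out each array. Leaving out genes with an identical value on all 4 arrays was added after seeing the data. Figures were drawn with matplotlib 3.10.9.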

Results

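Gene expression was compared between primary mouse articular chondrocytes that received an adenovirus carrying Rip3 and cells that received a control adenovirus, to find which transcripts differ when RIP3, a kinase that drives necroptotic cell death, is in excess. Each group held 2 biological replicates, 1 array per replicate, and 22087 genes had a row of their own. The labels do not say whether the replicates came from separate animals, so p-values measure the spread between these samples. Arrays of the same group correlated at r = 0.994 (Ad-C) and 0.993 (Ad-Rip3) over all rows, and arrays of different groups at 0.990 to 0.991.

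Ripk3 itself (Entrez 56532, probe set 17306906) was 40.3-fold higher in the Ad-Rip3 arrays. Its log2 signal was 7.11 ± 0.11 (SD, n = 2) with Ad-C and 12.44 ± 0.05 (SD, n = 2) with Ad-Rip3, a log2 fold change of 5.33 ± 0.11 (SE; limma adjusted p = 0.000117). This was the largest change among all 22087 genes, and the arrays, at 7.19 and 7.03 against 12.48 and 12.41, separated as their labels say. The Ad-Rip3 values lay near the highest signals of the arrays, 12.97 to 13.03. Whether signal there still follows RNA in proportion was not tested. Leaving out Ad-C replicate 1 or replicate 2 put the Ripk3 log2 fold change at 5.41 or 5.25. Leaving out Ad-Rip3 replicate 1 or replicate 2 put this log2 fold change at 5.30 or 5.37. In each of these fits the lone array of a group was assumed to vary like the arrays of the other group.

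After Ripk3, the largest rise was that of Mmp3 (stromelysin-1, a protease that degrades cartilage proteoglycan), which was 13.6-fold higher, from 6.52 ± 0.15 to 10.28 ± 0.13 (SD, n = 2 each; log2 fold change 3.76 ± 0.12 SE, adjusted p = 0.00113). Serpinb2 (plasminogen activator inhibitor-2) rose 9.03-fold, and its Ad-C level of 3.05 lay below the median level of all genes, 5.36. So did the Ad-C levels of Cxcl3 (4.31), Tnip3 (4.40), Ch25h (4.90) and U90926 (5.17). The chemokines Ccl5 and Cxcl3 rose 6.78-fold and 6.18-fold, and Mmp10 (stromelysin-2) rose 5.54-fold. U90926, Tnip3 (a binding partner of the NF-kB inhibitor A20), Saa3 (an acute-phase serum amyloid protein) and Ch25h (a cholesterol hydroxylase) rose 5.93-fold, 5.06-fold, 4.81-fold and 4.37-fold. Adjusted p-values in limma for these 8 genes ranged from 0.00281 to 0.0249. The falls were smaller. Npr3, the natriuretic peptide clearance receptor, fell 2.81-fold (log2 fold change -1.49 ± 0.10 SE, adjusted p = 0.0092) and Serpind1 (heparin cofactor II) fell 2.45-fold (adjusted p = 0.0249). Lrp4, Panx3, Sh3rf2 and Zfp185 fell 1.90-fold, 1.90-fold, 1.81-fold and 1.77-fold, with adjusted p-values between 0.0312 and 0.0423.

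**Figure D1:**
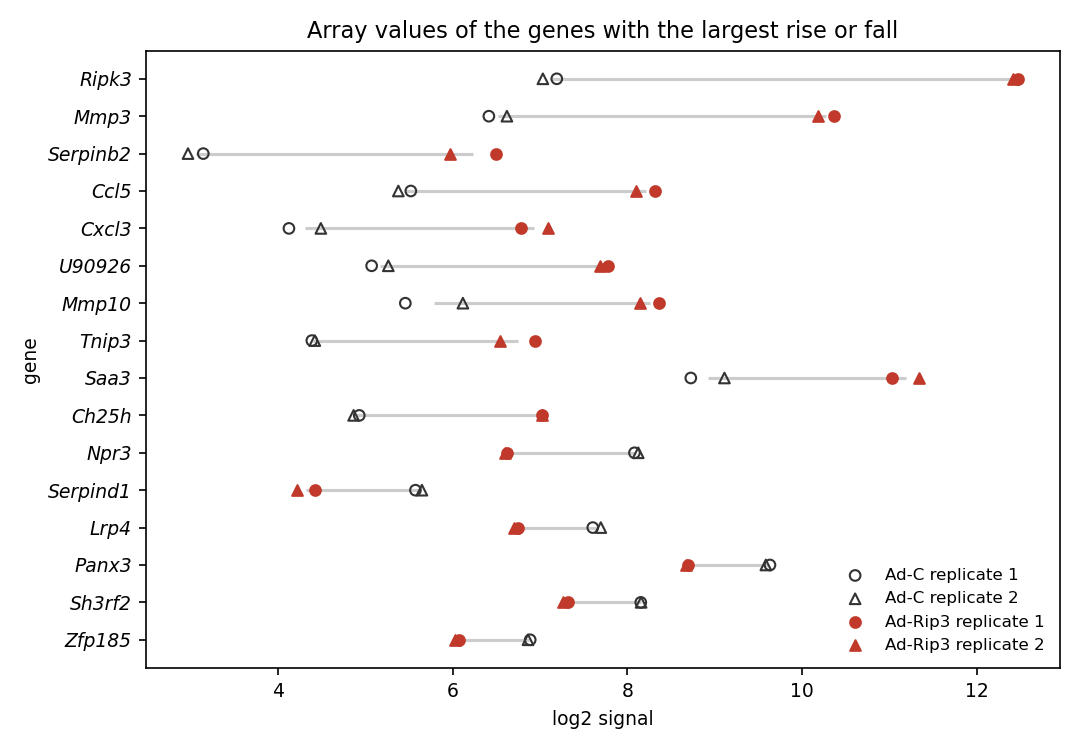
Log2 signal on each array (horizontal axis) of the 10 genes with the largest rise and the 6 named genes with the largest fall (vertical axis). Open symbols are Ad-C and filled symbols Ad-Rip3 arrays, circles replicate 1 and triangles replicate 2, and lines join the group means; in each gene both Ad-Rip3 arrays lie on the same side of both Ad-C arrays.

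With Ripk3 included, 82 genes passed an adjusted p of 0.05 in limma, 75 higher and 7 lower with Ad-Rip3, and 64 of the 82 changed by at least 2-fold. At an unadjusted p under 0.05 there were 3038 genes, where 1104 would be expected by chance. By size alone, 86 genes had group means at least 2-fold apart with no overlap between the groups, 80 higher and 6 lower; each of the other 2 ways of splitting the 4 arrays into pairs gave 1 such gene. Groups of 2 and 2 do not overlap in 33.3% of genes by chance, against 44.3% observed over all genes. A prior variance that follows signal level gave 879 genes, 474 higher and 405 lower, among them all 82, and centring each array on its median gave 325, 221 higher and 104 lower. Without Ad-C replicate 1 or without Ad-C replicate 2 the count was 2 (1923 and 1666 genes at an unadjusted p under 0.05), and without Ad-Rip3 replicate 1 or replicate 2 it was 0 (2736 and 2875 genes at an unadjusted p under 0.05).

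**Figure D2:**
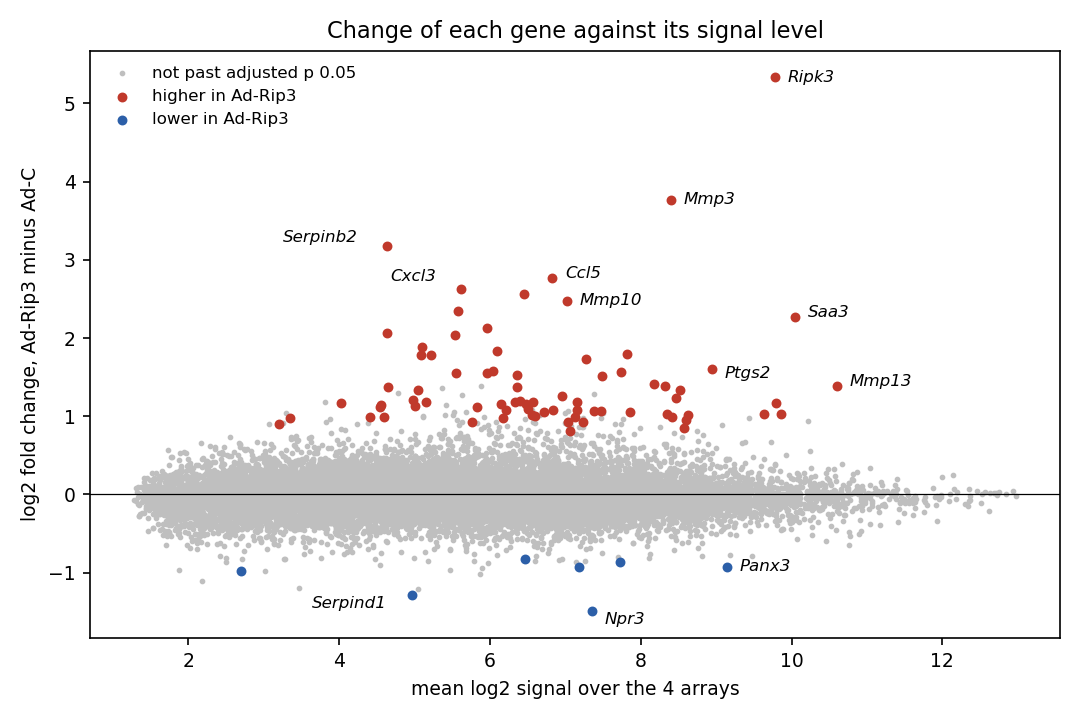
Log2 fold change of each of the 22087 genes (Ad-Rip3 minus Ad-C, vertical axis) against its mean log2 signal over the 4 arrays (horizontal axis). Red points are the 75 genes that passed an adjusted p of 0.05 with higher signal in Ad-Rip3, blue points the 7 with lower signal; Ripk3 stands apart at 5.33.

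Among the 21 matrix-degrading proteases, 4 rose, none fell and 17 did not pass. All 4 were matrix metalloproteinases: Mmp3, Mmp10, Mmp13 and Mmp12. Mmp13, the main collagenase for type II collagen, was already at 9.91 ± 0.03 with Ad-C and rose 2.62-fold to 11.30 ± 0.03 (SD, n = 2; limma adjusted p = 0.0116), and Mmp12 (macrophage elastase) rose 2.21-fold from a dim 3.98. The aggrecanase Adamts5 was at 7.55 ± 0.19 and 7.38 ± 0.13 (adjusted p = 0.649). Adjusted over the list alone, 5 members passed. The list as a whole lay above other genes (camera adjusted p = 5.85e-05; adjusted p = 0.408 with an estimated correlation), while its median log2 fold change was 0.13, against a mean of 0.49.

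The 32 inflammatory mediators and NF-kB targets had the highest median log2 fold change of the 23 lists, 0.65, with 27 members above 0. Of these genes 8 rose, none fell and 24 did not pass; adjusted over the list alone, 23 were higher and 1 was lower. Ccl5, Saa3, Ccl2 and Ptgs2 led the list. The monocyte chemoattractant Ccl2 rose 3.33-fold (log2 fold change 1.74 ± 0.16 SE, limma adjusted p = 0.0249), and Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose 3.03-fold (1.60 ± 0.12 SE, adjusted p = 0.0126). Il6 was dim, at 2.81 ± 0.42 and 3.37 ± 0.33 (adjusted p = 0.376). The camera test of the list gave an adjusted p of 2.69e-20, and an adjusted p = 0.267 with an estimated correlation. In the same arrays the macrophage and osteoclast markers had a median log2 fold change of 0.05, and none of 18 passed over all genes (camera adjusted p = 0.18). Cd68, a lysosomal protein abundant in macrophages, was 1.88-fold higher (limma adjusted p = 0.0689) and was the 1 member that passed adjusted over the list alone (adjusted p = 0.00799). With the dimmer genes left out, the 4 macrophage markers that remained had a median of 0.31 and passed camera at the preset correlation (adjusted p = 0.0108). Camera with an estimated correlation, run on the whole macrophage list, gave an adjusted p of 0.444.

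Cartilage matrix and chondrocyte identity genes were lower by small amounts. Of 26 members, 23 lay below 0, with a median log2 fold change of -0.15, but none passed over all genes or adjusted over the list alone. The type II collagen gene Col2a1 was at 12.57 ± 0.04 and 12.46 ± 0.06 (limma adjusted p = 0.717) and the aggrecan gene Acan at 12.41 ± 0.04 and 12.33 ± 0.01 (adjusted p = 0.805). Both lay near the highest signals of the arrays, 12.97 to 13.03, and whether signal there still follows RNA in proportion was not tested. Sox9, the transcription factor that maintains chondrocyte identity, differed by -0.40 ± 0.10 (SE, adjusted p = 0.182) and its partner Sox6 by -0.46 ± 0.11 (adjusted p = 0.172), whereas the matrix protein gene Chad was higher by 0.49 ± 0.10 (adjusted p = 0.131). With the prior variance that follows signal level, 5 members were lower and 2 higher. Among the lower were Sox9 and Sox6 (limma adjusted p = 0.00139 and 0.00868), and among the higher was Chad (0.00477). The list lay below other genes (camera adjusted p = 0.00134; adjusted p = 0.444 with an estimated correlation). Of 10 hypertrophy genes, 1 fell: Panx3, a channel protein of prehypertrophic and hypertrophic chondrocytes, from 9.61 ± 0.03 to 8.68 ± 0.02 (adjusted p = 0.0312). The median of the hypertrophy list was -0.24 (camera adjusted p = 0.00675; adjusted p = 0.408 with an estimated correlation), and adjusted over the list alone 4 members were lower and 1 was higher. Fibroblast and synovial lining markers went both ways in these arrays, with a median of 0.03 and 2 members higher and 1 lower adjusted over the list alone.

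Necroptosis and death-receptor genes, a list that leaves out Ripk3, were slightly higher. None of its 19 members passed over all genes or adjusted over the list alone, and their median was 0.09 (camera adjusted p = 0.00329; adjusted p = 0.425 with an estimated correlation). Mlkl, the substrate of RIP3 in necroptosis, was 1.99-fold higher with a wide spread, 5.42 ± 0.17 against 6.41 ± 0.41 (limma adjusted p = 0.143), and the TNF receptor gene Tnfrsf1b was 1.32-fold higher (adjusted p = 0.196). Without Ad-Rip3 replicate 1 the list no longer passed (camera adjusted p = 0.0563), and without Ad-Rip3 replicate 2 its median was 0.17. Among 28 interferon-stimulated genes 1 rose, over all genes and adjusted over the list alone: the chemokine Cxcl10, which was 2.99-fold higher (adjusted p = 0.00939). The median of that list was 0.16 (camera adjusted p = 0.00326; adjusted p = 0.408 with an estimated correlation), and the call was lost without Ad-Rip3 replicate 2 (adjusted p = 0.057, median 0.09) and among the brighter genes (adjusted p = 0.0965, median -0.02). Without Ad-C replicate 1 that list's median was 0.10.

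Cell cycle genes lay above 0 in 29 of 30 members with a median log2 fold change of 0.40. None passed over all genes with the constant prior variance, while 20 passed adjusted over the list alone, all higher. With the prior variance that follows signal level, 16 were higher over all genes and none lower. Rrm2, a ribonucleotide reductase subunit, was 1.74-fold higher (limma adjusted p = 0.0704) and Cdt1, a replication licensing factor, 1.57-fold higher (adjusted p = 0.089). The mean signal of the list was 7.68 and 7.48 on the Ad-Rip3 arrays, of which the lower lay 0.28 above the nearest Ad-C array. Its camera adjusted p was 4.02e-16 (adjusted p = 0.444 with an estimated correlation). The members moved together between replicates, with an estimated correlation of 0.75. The inflammatory list, whose estimated correlation of 0.0136 lay near the preset 0.01, also lost its camera call (adjusted p = 0.267). The size of the correlation alone therefore does not account for such losses. In the inflammatory list the unadjusted camera p went from 1.17e-21 to 0.0116. With an estimated correlation, camera reads its statistic on the residual degrees of freedom of the fit, here 2. A lost call therefore does not by itself show that the members of a list are correlated. The p53 targets were also higher, 15 of 16 members above 0 with a median of 0.28 and 7 past the threshold adjusted over the list alone (none over all genes; camera adjusted p = 1.02e-06; adjusted p = 0.408 with an estimated correlation). Trp53inp1 and Eda2r were 1.59-fold and 1.88-fold higher (limma adjusted p = 0.0705 and 0.089). With the prior variance that follows signal level, 8 p53 targets were higher over all genes and none lower.

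Among 19 immediate-early and AP-1 genes 1 rose: Dusp6, a phosphatase that is induced by and acts on ERK, 3.47-fold higher (limma adjusted p = 0.0249). The median of this list was 0.24, and 7 members were higher adjusted over the list alone (camera adjusted p = 5.98e-07; adjusted p = 0.408 with an estimated correlation). In the heat-shock list, of median 0.22, none of 11 passed over all genes and 3 were higher adjusted over the list alone (camera adjusted p = 0.00675; adjusted p = 0.408 with an estimated correlation). Its leading members were the near-identical copies Hspa1b and Hspa1a, 2.05-fold and 2.03-fold higher (adjusted p = 0.0731 and 0.0825), which share most of their sequence.

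The hypoxia and glycolysis list had a median of 0.11 over 15 genes, with none past the threshold over all genes and 4 higher and 1 lower adjusted over the list alone. The leading members were not glycolytic enzymes: the vasodilator peptide gene Adm was 1.83-fold higher (limma adjusted p = 0.0677) and the prolyl hydroxylase gene Egln3 1.82-fold higher (adjusted p = 0.108). Camera gave an adjusted p of 0.00675 (adjusted p = 0.444 with an estimated correlation), and 0.06 without Ad-Rip3 replicate 1; without Ad-Rip3 replicate 2 the median was 0.17. Cholesterol biosynthesis genes were lower in 12 of 15 members, with a median of -0.18 and none past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.00909; adjusted p = 0.444 with an estimated correlation; adjusted p = 0.117 without Ad-Rip3 replicate 2). Fdps and Cyp51, both enzymes of that pathway, differed by -0.27 and -0.22.

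The remaining 11 lists did not pass camera at the preset correlation. TGF-beta and YAP targets went both ways, with 3 higher and 5 lower adjusted over the list alone and none past the threshold over all genes; Tgfb2 and Tagln differed by -0.62 and -0.55 (limma adjusted p = 0.077 and 0.122). The median of that list was -0.00202 (camera adjusted p = 0.512, and 0.0172 with a robust variance trend). The NRF2 list had a median of 0.10 (camera adjusted p = 0.0565; adjusted p = 0.444 with an estimated correlation), led by Gsr and Mt2 at 0.35 and 0.34, with no member past the threshold over all genes or adjusted over the list alone. It passed camera with the intensity trend, plain or robust (adjusted p = 0.00442 and 0.00625), with the dimmer genes left out (0.0373) and after quantile normalization (0.0259). The median of the NRF2 list was 0.17 without Ad-Rip3 replicate 2 and -0.00273 without Ad-Rip3 replicate 1. Trib3 and Xbp1 of the unfolded protein list differed by -0.39 and -0.31, Ndufa2 and Cycs of oxidative phosphorylation by -0.26 and 0.18, and the ribosomal protein genes Rps18 and Rpl10a by -0.29 and -0.27; none of these 6 passed. Medians of these 3 lists were -0.02, -0.02 and -0.06 (camera adjusted p = 0.213, 0.448 and 0.188), and no member passed over all genes or adjusted over the list alone; the ribosomal list passed camera with the intensity trend (adjusted p = 0.0481). With 1 array left out, medians ran from -0.03 to 0.06 for TGF-beta and YAP targets, from -0.07 to 0.00165 for the unfolded protein list and from -0.05 to -0.00378 for oxidative phosphorylation.

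Markers of other cell types gave 2 calls. Cd34, a surface protein of stromal and endothelial progenitors, rose 2.13-fold (limma adjusted p = 0.0249), and Fabp4, a fatty acid carrier of adipocytes and macrophages, rose 2.92-fold (adjusted p = 0.0382). Their lists, fibroblast and synovial lining markers and adipocyte and muscle markers, had medians of 0.03 and -0.04 (camera adjusted p = 0.512 and 0.91); in the adipocyte and muscle list the mean, 0.08, and the camera direction were positive. Endothelial, blood cell and osteoblast markers had medians of 0.09, 0.05 and -0.05 with no member past the threshold (camera adjusted p = 0.258, 0.491 and 0.448). With 1 array left out, medians ran from -0.09 to 0.09 (fibroblast), -0.12 to 0.10 (adipocyte and muscle), 0.01 to 0.12 (endothelial), -0.00272 to 0.14 (blood cell) and -0.13 to -0.00713 (osteoblast). The leading members of these last 3 lists were Tie1 and Pecam1 (0.37 and 0.15), S100a8 and S100a9 (0.23 and -0.21), and Sp7 and Bglap (-0.33 and -0.17); Tyrobp, of the macrophage list, differed by -0.40. In all, 12 of 23 lists passed camera at the preset correlation, 9 upward and 3 downward; none passed with an estimated correlation, and 4 passed fry (matrix-degrading proteases, inflammatory mediators, immediate-early genes and hypertrophy). The mixed form of fry, which asks whether members change in either direction, was passed by 19 of the 23 lists. Over all genes, the prior variance that follows signal level called 19 inflammatory, 3 necroptosis, 3 heat-shock and 2 NRF2 genes higher. It called 2 unfolded protein genes lower. Hypoxia and glycolysis gave 4 higher and 1 lower, and TGF-beta and YAP targets 2 higher and 4 lower. The cholesterol, oxidative phosphorylation and ribosomal lists had none.

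**Figure D3:**
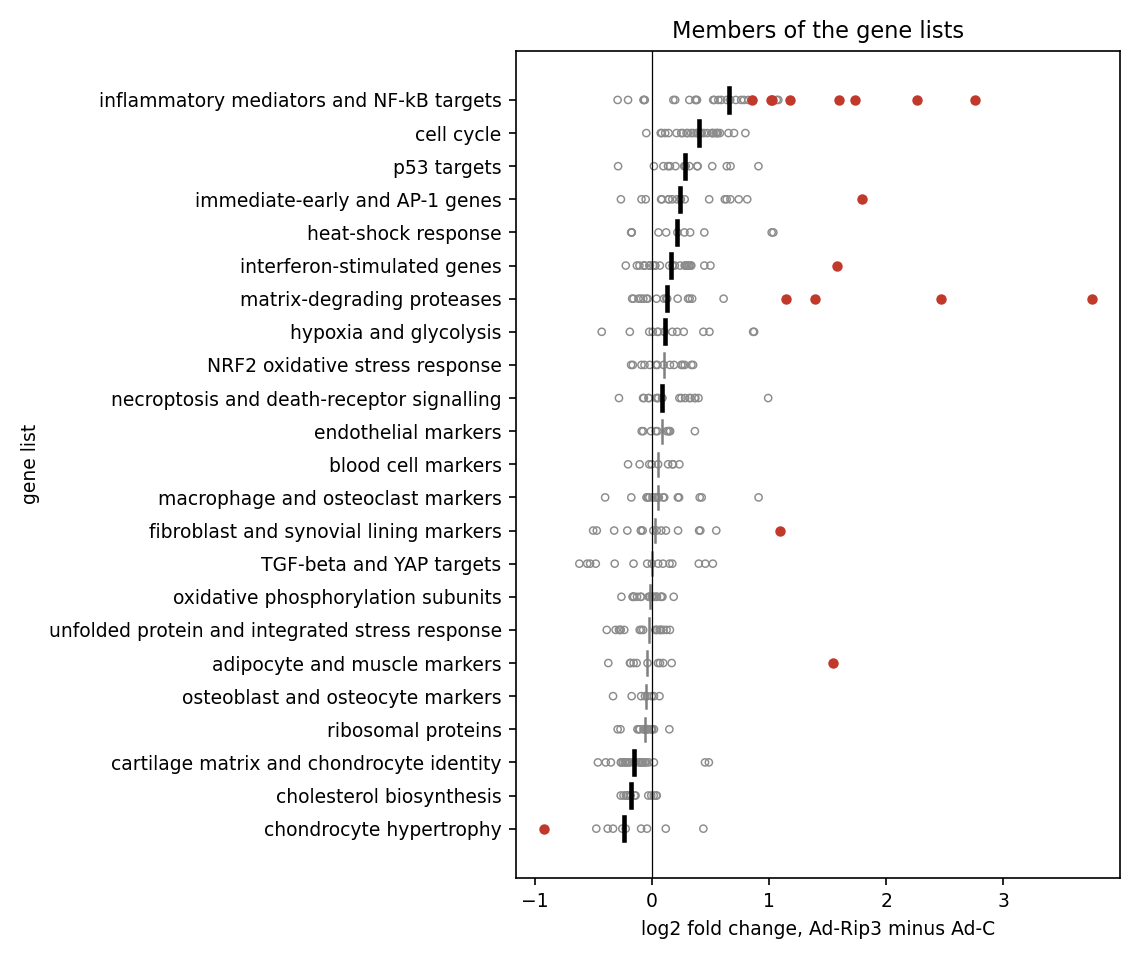
Log2 fold change (Ad-Rip3 minus Ad-C, horizontal axis) of each measured member of the 23 lists (vertical axis, ordered by median). Filled red points passed an adjusted p of 0.05 over all genes, open points did not, and vertical bars mark medians, black and thick for the 12 lists past camera at the preset correlation; the inflammatory list has the highest median, 0.65, and the hypertrophy list the lowest, -0.24.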

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

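All tests of explanations in this part were chosen after the results were seen. Of the 8779 array rows that name no gene or several, which the comparison did not use, 4 passed an adjusted p of 0.05 in a limma fit over every row, all higher with Ad-Rip3. Rows 17346528 and 17439830, which the annotation does not list, were higher by 2.41 and 1.21 on the log2 scale, from 6.20 ± 0.13 to 8.61 ± 0.01 and from 10.34 ± 0.05 to 11.55 ± 0.08 (SD, n = 2). Rows 17337122 and 17356427, which several genes share, were higher by 1.98 and 1.54.

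The rise of the inflammatory and NF-kB list (median 0.65, bootstrap interval 0.45 to 0.84 over genes) was not carried by 1 array, since the lowest median with any array left out was 0.61. Macrophages in the Ad-Rip3 cultures stay open as a source: the macrophage and osteoclast list had a median of 0.0489 (interval -0.02 to 0.16; 0.02 without Ad-C replicate 2 to 0.11 without Ad-C replicate 1), against 0.65, but its 4 members above the median level of all genes had a median of 0.31 (interval 0.06 to 0.91) and passed camera among the brighter genes (adjusted p = 0.0108). Those 4 went from 6.54 to 7.45 (Cd68), 6.51 to 6.73 (Acp5), 5.43 to 5.83 (Cd14) and 5.52 to 5.58 (C1qa), chosen for mention after their values were seen. Their interval spans the lowest to the highest of the 4 changes. Dimmer members, likewise chosen, went from 3.66 to 4.08 (Adgre1), 3.70 to 3.81 (Ptprc), 4.61 to 4.64 (Csf1r) and 4.48 to 4.07 (Tyrobp). Of all 18 members, 12 lay above 0 and 6 below (camera adjusted p = 0.18, and 0.444 with an estimated correlation). A larger virus dose or a stronger response to the vector cannot be told apart from Rip3 itself, because each virus is 1 group; interferon-stimulated genes had a median of 0.16 (interval -0.00475 to 0.29; 0.09 without Ad-Rip3 replicate 2 to 0.20 without Ad-Rip3 replicate 1). A response to excess RIP3 is the explanation the design names, and it stays open with these.

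The higher level of the cell cycle list remained under other scalings of the arrays, with a lowest median of 0.38 against 0.40. The array medians already lay between 4.97 and 5.05, so these scalings could move it only a little. They therefore cannot decide whether scaling played a part. Whether cultures of 1 group can differ by as much stays open: the gap between the nearest arrays of the 2 groups was 1.40 times the largest range within a group (0.28 against 0.20), and 2 arrays per group do not give that range well. A response to Rip3 stays open beside it.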

How the results depend on the processing

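The count of 82 genes differed between settings. It was 879 with an intensity trend in the prior, 869 with a robust trend, 875 (469 higher, 406 lower) with the dimmer genes left out and 325 (221 higher, 104 lower) after median centring, where the prior degrees of freedom were 7.74, 7.76, 6.29 and 10.6 instead of 3.92; the last 2 also change the genes tested or the scaling, and what moved their counts was not separated. Median within-group SDs went from 0.154 in genes under a level of 3 to 0.0528 above 9. Testing every row gave 29 (24 of the 82 among them; the cause was not tested). With 1 array left out, which leaves 1 residual degree of freedom, the count ranged from 0 to 2, the Ripk3 log2 fold change from 5.25 to 5.41, and the count of genes 2-fold apart from 86 to 122. Averaging a gene's rows, quantile normalization and leaving out constant genes (chosen after seeing the data) gave 87, 80 and 90. Whether the replicate numbers pair the samples is not stated. Same-numbered arrays' deviations from their group means correlated at 0.0057 over genes, which shows no shared shift but not how the samples were prepared. The replicate block, also with 1 residual degree of freedom, gave 16 genes. The 12 lists past camera became 0 with an estimated correlation and 4 with fry, and numbered 10 to 14 under the other alternatives run for lists, the block included (12); lists were not run over every row, and with the dimmer genes left out the endothelial and blood cell lists were not tested. Of the named genes, Bglap changed sign and ranged from -0.63 to 0.28 with 1 array left out, the latter without Ad-C replicate 2; its Ad-C arrays differed by more than any other named gene's. The median log2 fold change of all genes was -0.00739, and -0.0308 after median centring. Without detection calls, signal over background limits what can be said of dim genes such as Il6.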

Other observations

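Genes in this part, and the tests on the domain between Dlk1 and Dio3, were chosen after their values were seen. Among the 82 genes were growth factors and their regulators that no list held. The ErbB receptor ligands Ereg and Nrg1 rose 2.66-fold and 2.88-fold, Errfi1, a feedback inhibitor of ErbB signalling, rose 2.62-fold, and Kitl (stem cell factor), Inhba (the activin beta A subunit) and Fgf7 rose 4.10-fold, 2.40-fold and 2.12-fold (limma adjusted p from 0.00281 to 0.0312). The G1 cyclins Ccnd1 and Ccne1 rose 2.00-fold and 1.99-fold (adjusted p = 0.0426 and 0.0454). Acute-phase and complement genes Hp and Cfb rose 3.58-fold and 2.92-fold, the surface proteins Cd44, Pdpn and Itga2 rose 2.11-fold, 2.03-fold and 2.53-fold, and the IL-13 receptor genes Il13ra1 and Il13ra2 rose 1.90-fold and 2.25-fold. H2-K1 (MHC class I) rose 2.10-fold, a gene with close relatives in its family.

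Genes of the imprinted domain from Dlk1 to Dio3, in the gene order of the RefSeq table, were lower together. Of 55 genes with a row, 52 lay below 0, with a median log2 fold change of -0.44 (bootstrap interval -0.46 to -0.35 over genes). None passed over all genes in limma with a constant prior variance, 16 passed with an intensity trend, all lower, and 34 had an unadjusted p under 0.05. The long noncoding RNAs Rian and Meg3 differed by -0.44 and -0.34 and the protein-coding gene Dlk1 by -0.44, while Dio3 differed by 0.17. Among 20830 runs of 55 neighbouring genes elsewhere in the genome, the lowest median was -0.12.

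A loss of signal in microRNA rows in general argues poorly as the cause, since 436 microRNA genes outside the domain had a median of -0.0340 (interval -0.05 to -0.01), against -0.44 for the 43 inside. The shift did not rest on 1 array either, as the medians without each array ran from -0.43 to -0.36. Many of these rows may read parts of the same long transcripts, so they are not independent. The 52 of 55, the bootstrap interval and the comparison with other runs of genes therefore overstate the evidence. The domain was also picked for its low values, and the other runs were not. A lower output of the domain after Rip3 delivery is a hypothesis found and examined on the same 4 arrays.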
